A study of Mus musculus with 12 samples.

How the data were processed

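Palatal shelves of gestational day 12 mouse embryos were profiled by RNA sequencing in 12 libraries, 3 for each of the knockout, control, AzadC and vehicle groups, each a pool of 2 embryos of one genotype. The mRNA libraries were made with a NuGen kit, per the labels' protocols. The dose, route and time of AzadC and its vehicle, the Cre driver, the deleted exons and the strand setting of the counting are not given in the sources used here.

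The deposited values are expected counts per gene from RSEM, 56691 genes in each library, per the submitters' processing notes and the file headers. Those notes name FastQC, Trim Galore, STAR 2.7.0, RSEM 1.3.1, DESeq2 and the mouse build mm10. RSEM shares reads that fit several genes between them, so that a value need not be whole. Of all values per library, zeros included, 90.6% to 93.1% were whole within 0.005. Only 21014 to 23813 genes per library had a count, so the share among nonzero values was lower. Genes with near-identical copies (Xlr3 and Xlr4, Tuba3a and Tuba3b, the adult globins) are therefore uncertain one by one. Symbols and coordinates came from GENCODE M21, which holds 52073 (91.8%) of the gene IDs; 2639 genes without a symbol kept their IDs, and 77 symbols stood on more than 1 row. Group labels came from the sample labels. The replicate numbers do not pair the samples. No replicate pair of a group differed by less than the sampling noise, so each library counted as 1 replicate.

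The expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group (17335) were scaled by TMM (factors 0.985 to 1.01) and fitted with 1 mean per group over all 12 libraries (estimateDisp, glmQLFit, glmQLFTest). The common coefficient of biological variation was 0.152. Benjamini-Hochberg adjusted p below 0.05 over all genes was the threshold. The contrasts were knockout against control, AzadC against vehicle, vehicle against control, and the difference of the first 2. SEs are the absolute log2 change divided by the square root of the F statistic of its test, and CPM values are TMM-scaled. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over that group; with 1 to 3 counts, the ratio has an exact 95% interval for counting error only. Depth was 12640536 to 33113790 counts per library, and intervals and floors cover counting error only.

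The 30 gene lists were fixed beforehand: DNA methylation machinery, methylation-silenced germline genes, imprinted genes, clustered protocadherins, p53 targets, interferon response, S-phase, G2/M, palatal and facial mesenchyme regulators, osteogenic, chondrogenic, myogenic, epithelial, endothelial, mural cell, erythroid, macrophage and leukocyte, neuronal, Schwann and glial, and melanocyte genes, Hedgehog, Wnt/beta-catenin, BMP and TGF-beta, and FGF-ERK targets, Hox genes, immediate early genes, integrated stress response, hypoxia and glycolysis, mitochondrially encoded and sex-linked reporter genes. They hold 1005 different genes, 6 of which are not among the gene symbols used here. Lists were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether members move one way on balance. Lists that passed camera are given with their counts over all genes and adjusted over the list alone, and the others mostly with the camera result in the knockout. A list score is the mean of the members' log2 CPM centred on the mean of all libraries.

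Also fixed beforehand was the rule for named genes: the methylation enzymes Dnmt1, Dnmt3a, Dnmt3b, Uhrf1 and Tet1; the 8 highest and 8 lowest fold changes past the threshold for the knockout and AzadC contrasts and 5 for the others, with a mean above 1 CPM and, except for the difference, separated libraries, leaving out Gm and Rik names, pseudogenes, Xist, Tsix and Y-linked genes; and up to 4 members per list with the smallest adjusted p, or 2 where none passed. The text names the extremes, except for a result that is not reported here, and a part of the list members, chosen after their values were seen.

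The scripts were tested on simulated data with 200 changed genes among 17335. At 1.5-, 2- and 4-fold, edgeR recovered 43.3%, 65.7% and 92.4% in the knockout comparison, 46.3%, 73.1% and 87.9% in AzadC against vehicle, 49.3%, 73.1% and 95.5% in vehicle against control, and 22.4%, 55.2% and 84.8% for the difference. Of its calls 2.1%, 4.5% and 0.6% were false in the first 3, and of those by DESeq2 10.3%, 14% and 12.8%.

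Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter, a mean above 1 CPM, only the groups compared, the replicate number as a block, the summed Y-linked level as a covariate, a test against a 1.2-fold change, and leaving out each library. Chosen after seeing the data were the knockout against the vehicle libraries and the myogenic score as a covariate. A range of adjusted p over the alternatives covers these settings except the fits with 1 library left out, which can give higher values. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.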

Results

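RNA was sequenced from the palatal shelves of mouse embryos, the paired outgrowths of the upper jaw that form the roof of the mouth, at gestational day 12. The 12 libraries fell into 4 groups of 3. The knockout group had a conditional knockout of Dnmt1, the enzyme that copies DNA methylation onto newly made DNA, and the control group was untreated and wild type. A further group of wild type embryos was exposed to AzadC, that is 5-aza-2'-deoxycytidine, a cytosine analogue that blocks DNA methyltransferases, and the vehicle group was given its vehicle. Each library came from 2 pooled embryos of one genotype and a group from 6, per the labels' protocols, while the design text of the series speaks of 3 pooled animals. The gene totals ran from 12640536 expected counts in AzadC 1 to 33113790 in control 1. Each library had between 15109 and 17250 genes with 10 or more counts. Levels are given as CPM, counts scaled to a common library total, with the SD over 3 libraries. The p-values and intervals cover the spread between these pooled libraries or the counting of reads, and single embryos were not measured. Principal components of the 500 most variable genes placed the 3 knockout libraries at 57.3 to 68.2 on the first axis, which held 64.9% of the variance, and the 9 others between -25.4 and -14.6.

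**Figure D1:**
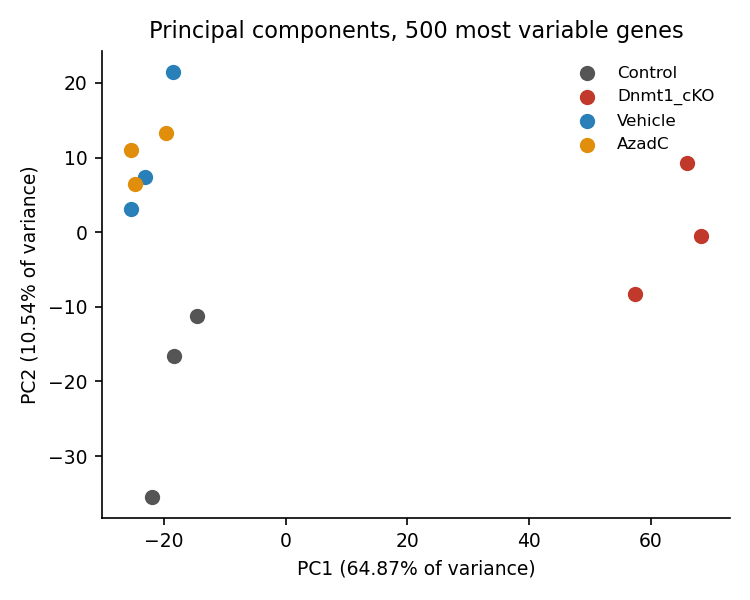
Principal component scores of the 12 libraries from log2 CPM of the 500 most variable genes, PC1 on the horizontal and PC2 on the vertical axis, 1 point per library coloured by group. The knockout libraries lie at 57.3 to 68.2 on PC1 and all others below 0.

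The first comparison, knockout against control, asked which transcripts differ in palatal shelves when Dnmt1 is deleted. Dnmt1 itself (ENSMUSG00000004099, chromosome 9, 20907209 to 20959888, minus strand, mm10) was read first, in every library. It stood at 201, 179.6 and 191 CPM in the knockout libraries and at 286, 278 and 258 CPM in the control libraries, a log2 change of -0.52 (SE 0.07, edgeR adjusted p = 0.000369). The change was -1.24 against the vehicle libraries, a contrast added after the data were seen (edgeR adjusted p = 1.62e-07). Over the alternatives to the control contrast other than leaving out 1 library, the adjusted p ran from 4.07e-10 to 0.0084. Reads of Dnmt1 remained in the knockout, and the deleted exons and the cells that recombine are not given in the sources used here. The vehicle libraries had 452, 451 and 448 CPM and the AzadC libraries 408, 482 and 411 CPM, so that the 3 control libraries lay below all 6 of these. Of the other methylation enzymes and their partners, Dnmt3a changed by -0.05 log2 units (edgeR adjusted p = 0.640), Dnmt3b by 0.36 (0.0550) and Tet1 by 0.06 (0.721), none past the threshold. Uhrf1, which brings Dnmt1 to hemimethylated DNA, rose by 0.35 log2 units (SE 0.08, edgeR adjusted p = 0.0134), but lost the call without control 2 (0.0616) or knockout 1 (0.0573). It also lost it against a 1.2-fold change (0.364) and, in settings added after the data were seen, against the vehicle libraries (0.407) or with the myogenic score as a covariate (0.162; range over the alternatives 0.000879 to 0.407). Dnmt3b passed with DESeq2 (adjusted p = 0.0357, over the alternatives up to 0.956). In the DNA methylation machinery list 2 of 21 genes were higher and 2 lower, and 3 and 2 when adjusted over the list alone (camera adjusted p = 0.519).

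**Figure D2:**
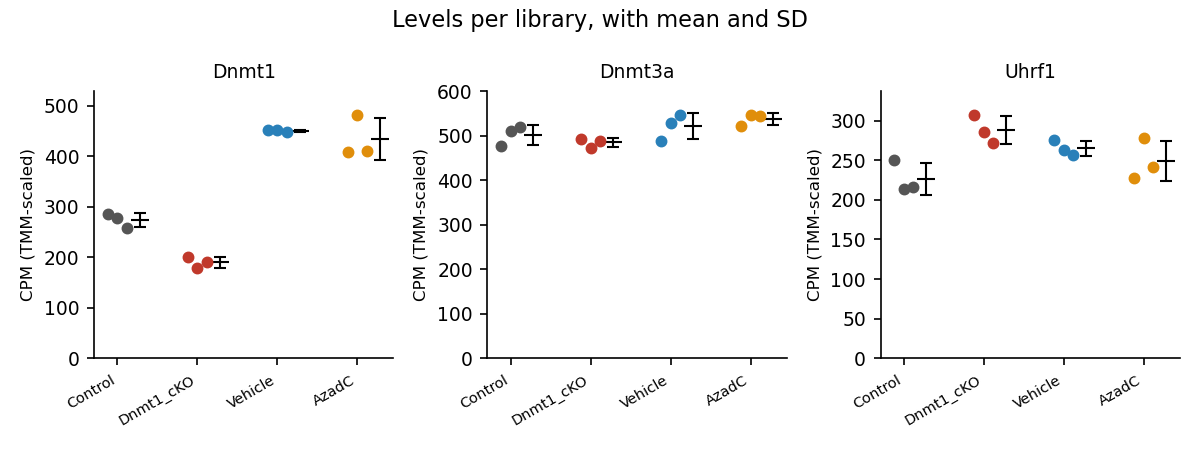
TMM-scaled CPM of Dnmt1, Dnmt3a and Uhrf1 in each library by group, points for libraries and bars for the mean and SD (n = 3). Dnmt1 averaged 190.5 CPM in the knockout, 274 in the control, 450.5 in the vehicle and 434 in the AzadC group.

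Genes of the germ line that are normally silenced by DNA methylation in body cells rose most. Dazl, an RNA-binding protein of germ cells (chromosome 17, 50279395 to 50293636), had 0 counts in the control libraries and 89.3 ± 27.5 CPM (SD, n = 3) in the knockout, at least 2300-fold higher against a floor of 3 counts over the control group. Sohlh2, a transcription factor of early germ cells, was at least 1530-fold higher, and the testis-associated Tex13b and Tex19.1 at least 380-fold and 316-fold. Tuba3b, a testis tubulin, and the X-linked Xlr3c had 1 control count each, with ratios of 3670 (95% counting interval 659 to 145000) and 2220 (397 to 87500). Both have near-identical copies, so their own levels are uncertain. The other large rises were Dcaf8l at no less than 924-fold, the gene ENSMUSG00000120900 (no symbol matched) at 458-fold or more, and Strc, stereocilin of the inner ear, at 312-fold or more, each with 0 control counts. Stag3, a meiotic cohesin, rose from 15.2 ± 2.22 to 72 ± 10.7 CPM. This was a log2 change of 2.24 (SE 0.13, edgeR adjusted p = 1.34e-07). Across the methylation-silenced germline list, 42 of 46 tested genes were higher, and 43 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.23e-38, and adjusted p = 0.0302 with an estimated correlation). Its median fitted log2 change was 5.56, or 4.49 with the 12 genes that had 0 control counts set at their bounds. The full list held 61 genes, and the filter kept those expressed in any 1 group. The 12 could therefore pass it through their knockout counts alone. The share of tested genes that were higher and the list test are thus partly set by the filter.

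Genes of the integrated stress response, which cells use when amino acids are short or protein folding is disturbed, rose with the knockout. The list call was lost with an estimated correlation (adjusted p = 0.0582 with an estimated correlation). The amino acid transporter Slc7a5 went from 24.8 ± 2.83 to 103.9 ± 14.8 CPM, a rise of 2.06 log2 units (SE 0.13, edgeR adjusted p = 3.21e-07), and Asns, asparagine synthetase, rose by 1.76 (SE 0.12, edgeR adjusted p = 1.04e-06). Chac1, which degrades glutathione, rose by 4.76 (SE 0.40, edgeR adjusted p = 5.92e-06). In all 25 of 30 list genes were higher, and 26 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 5.44e-21, and adjusted p = 0.0582 with an estimated correlation). Against the vehicle libraries, added after the data were seen, 22 were higher (camera adjusted p = 3.61e-23, and 0.0323 with an estimated correlation). Among p53 target genes 9 of 35 were higher and 1 lower, and 10 and 1 when adjusted over the list alone (camera adjusted p = 0.00762, and adjusted p = 0.0718 with an estimated correlation). Against the vehicle libraries 8 were higher and 0 lower (camera adjusted p = 0.00159, and 0.0323 with an estimated correlation). The receptor gene Eda2r rose by 3.16 log2 units (SE 0.35) and Sesn2, which is also on the stress response list, by 1.22 (SE 0.16), with edgeR adjusted p of 6.79e-05 and 0.000295.

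Macrophage genes were also higher in the knockout. Csf1r, the receptor for colony stimulating factor 1, rose from 18 ± 2.4 to 92.1 ± 7.64 CPM, or by 2.35 log2 units (SE 0.14, edgeR adjusted p = 1.78e-07), and Adgre1, which encodes the F4/80 antigen, by 2.46 (SE 0.18, edgeR adjusted p = 1.15e-06). Of 31 macrophage and leukocyte genes 24 were higher and 1 lower, the same counts as when adjusted over the list alone (camera adjusted p = 5.44e-21, and adjusted p = 0.0302 with an estimated correlation). In the interferon response list 9 of 47 genes were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.00292, and adjusted p = 0.625 with an estimated correlation). Without control 2 there were 4 higher interferon genes, and without control 1 the count adjusted over the list alone was 17. B2m, the light chain of class I histocompatibility molecules, rose by 0.54 log2 units (SE 0.08, edgeR adjusted p = 0.000839).

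Cartilage and bone genes were lower in the knockout than in the control libraries. These list calls were lost with an estimated correlation (adjusted p = 0.283 and 0.266 with an estimated correlation). Sox9, the master regulator of cartilage, went from 101.5 ± 31 to 29.2 ± 5.05 CPM. This was a log2 change of -1.80 (SE 0.18, edgeR adjusted p = 3.01e-05), and Col2a1, the main cartilage collagen, fell by 1.96 (SE 0.31, edgeR adjusted p = 0.00113). Runx2 and Sp7, transcription factors of bone formation, fell by 1.16 (SE 0.14) and 1.98 (SE 0.27), with edgeR adjusted p of 0.000132 and 0.000329. Of 28 chondrogenic genes 21 were lower and 1 higher, and 23 and 1 when adjusted over the list alone (camera adjusted p = 1.02e-10, and adjusted p = 0.283 with an estimated correlation). Of 30 osteogenic genes 14 were lower and 2 higher, and 20 and 3 when adjusted over the list alone (camera adjusted p = 3.91e-07, and adjusted p = 0.266 with an estimated correlation). The 8 named genes with the lowest log2 change were Ibsp (-6.69), Scin (-6.06), Acan (-4.63), Matn4 (-4.22), Cnmd (-4.00), BC006965 (-3.79), Csmd3 (-3.78) and Ltbp2 (-3.73), among them a bone sialoprotein and the cartilage matrix genes Acan, Matn4 and Cnmd. Without control 2 the first 6 stood at -5.76, -5.03, -3.46, -3.51, -2.90 and -2.97. Without knockout 1 Ibsp and Scin stood at -6.07 and -7.76, and without knockout 3 Ibsp at -10.46. Against the vehicle libraries, a contrast added after the data were seen, 7 of these 8 did not pass (edgeR adjusted p 0.0583 to 0.989), nor did Runx2 (0.270) or Sp7 (0.131), while Sox9 (-1.67, 6.12e-05) and Col2a1 (-1.67, 0.00376) did. Acan also failed with limma-voom (adjusted p = 0.102, over the alternatives 2.12e-10 to 0.190). In that contrast 6 of 28 chondrogenic genes were lower, with a median of -0.74 in place of -1.88 (camera adjusted p = 2e-04, and adjusted p = 0.564 with an estimated correlation). Of 30 osteogenic genes 5 were higher and 3 lower there (camera adjusted p = 0.34). With the myogenic score as a covariate, also added afterwards, 21 chondrogenic and 14 osteogenic genes were lower.

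Genes of cell division were higher in the knockout than in the control libraries by small amounts. Both list calls were lost with an estimated correlation (adjusted p = 0.299 for G2/M and 0.449 for S-phase genes with an estimated correlation). Ncapd2, a condensin subunit, rose by 0.38 log2 units (SE 0.06, edgeR adjusted p = 0.00184) and Cdc20, which starts anaphase, by 0.48 (SE 0.09, edgeR adjusted p = 0.00246). Neither passed against the vehicle libraries, nor Ncapd2 against a 1.2-fold change (edgeR adjusted p over the alternatives 1.27e-06 to 0.718 for Ncapd2 and 7.62e-06 to 0.4999 for Cdc20). In the G2/M list 32 of 51 genes were higher, and 44 when adjusted over the list alone (camera adjusted p = 5.48e-17, and adjusted p = 0.299 with an estimated correlation). In the S-phase list 9 of 49 were higher, and 18 when adjusted over the list alone (camera adjusted p = 8.39e-08, and adjusted p = 0.449 with an estimated correlation). DESeq2 called 16 S-phase genes higher and voom 10. Leaving out control 2 left 12 G2/M and 4 S-phase genes, and leaving out knockout 2 left 10 and 3. Adjusted over the list alone, S-phase genes numbered 8 without control 2, 8 without knockout 2, and 10 without knockout 1 or knockout 3. Against the vehicle libraries 0 of 51 G2/M genes passed by edgeR, DESeq2 or voom, with 0 at an unadjusted p below 0.05. For S-phase genes that count was 0 of 49 by each tool, with 1 higher and 4 lower at an unadjusted p below 0.05.

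Muscle genes varied widely between libraries of one group. Neb, a protein of the muscle thin filament, had 40.8 ± 30 CPM in the knockout and 3.98 ± 1.78 in the control group, a log2 change of 3.32 (SE 0.75, edgeR adjusted p = 0.00989). Pax7, a factor of muscle precursors, changed by 4.12 (SE 0.99, edgeR adjusted p = 0.0141). Of 38 myogenic genes 24 were higher, and 37 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 8.5e-10, and adjusted p = 0.505 with an estimated correlation). DESeq2 called 23 higher and 1 lower, and voom 9 higher. The mean centred log2 level of the list was 3.06, 1.94 and 0.61 in the knockout libraries and 0.01, -0.90 and -3.20 in the control libraries. Only 2 genes passed without control 2, 4 without control 3, 2 without knockout 1 and 9 without knockout 2, and 19 adjusted over the list alone without knockout 1. Pax7 lost its call without control 2 (edgeR adjusted p = 0.0559) or knockout 1 (log2 change 3.39, 0.0555) and stood at 4.97 without control 1. Neb stood at 2.64 without knockout 1. Against the vehicle libraries 0 of 38 myogenic genes passed by edgeR, DESeq2 or voom, with 10 higher at an unadjusted p below 0.05, while the list passed upward (median 1.61, camera adjusted p = 1.59e-07, and adjusted p = 0.564 with an estimated correlation). Neb and Pax7 did not pass there or with the myogenic score as a covariate, nor Pax7 with limma-voom (adjusted p over the alternatives 1.27e-08 to 0.223 for Neb and 4.39e-07 to 0.205 for Pax7).

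Regulators of the palatal and facial mesenchyme were lower on balance than in the control libraries. That call did not hold with an estimated correlation (adjusted p = 0.266 with an estimated correlation). Foxf2, a forkhead factor of the palatal mesenchyme, went from 174.8 ± 21 to 97.8 ± 18 CPM. This was a log2 change of -0.84 (SE 0.13, edgeR adjusted p = 0.00103), and the homeobox gene Msx2 fell by 2.56 (SE 0.40, edgeR adjusted p = 0.00104). Msx2 did not pass against the vehicle libraries (edgeR adjusted p over the alternatives 1.57e-09 to 0.5848). In this list 15 of 62 genes were lower and 1 higher, and 17 and 2 when adjusted over the list alone (camera adjusted p = 0.00193, and adjusted p = 0.266 with an estimated correlation). Among BMP and TGF-beta targets 8 of 28 were lower and 1 higher, and 11 and 2 when adjusted over the list alone, or 7 lower without control 2 (camera adjusted p = 0.00218, and adjusted p = 0.266 with an estimated correlation). Id2 fell by 0.60 (SE 0.08, edgeR adjusted p = 0.000429). Hypoxia and glycolysis genes had 10 of 37 lower and 2 higher, and 14 and 2 when adjusted over the list alone (camera adjusted p = 0.00292, and adjusted p = 0.477 with an estimated correlation). 4, 6 and 5 were lower without control 1, knockout 1 and knockout 2, and adjusted over the list alone 7 without control 1 and 9 without knockout 2. Endothelial genes had 4 of 30 lower, also when adjusted over the list alone, or 8 in that count without knockout 1 (camera adjusted p = 0.00292, and adjusted p = 0.517 with an estimated correlation). Melanocyte genes had 2 of 6 higher, also over the list alone (camera adjusted p = 0.00767, and adjusted p = 0.266 with an estimated correlation), and FGF-ERK targets 1 of 19 higher and 1 lower, or 5 and 1 when adjusted over the list alone (camera adjusted p = 0.0293, and adjusted p = 0.526 with an estimated correlation). Against the vehicle libraries the palatal list (12 lower and 3 higher, camera adjusted p = 0.159), BMP and TGF-beta targets (5 and 1, 0.183) and hypoxia genes (2 and 2, 0.113) did not pass, and 1 endothelial gene was lower (0.05). The median of the palatal list was -0.03 there and -0.25 against control, Foxf2 passed there too (-0.86), and whether the contrasts differ was not tested for these lists.

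Imprinted genes, of which one parental copy is silenced by methylation, moved both ways. Mest, paternally expressed, rose by 0.63 log2 units (SE 0.08, edgeR adjusted p = 0.000218) and Grb10 fell by 0.31 (SE 0.06, edgeR adjusted p = 0.00325, and 2.98e-06 to 0.448 over the alternatives, the last against a 1.2-fold change). Of 54 imprinted genes 8 were higher and 9 lower, and 8 and 11 when adjusted over the list alone (camera adjusted p = 0.431). The higher count was 3 without control 2, 5 without control 3 or knockout 1 and 4 without knockout 2, and the lower count 5 without knockout 2. Adjusted over the list alone, 4 were higher without knockout 2, and 7 lower without control 2, knockout 2 or knockout 3. The clustered protocadherins had 7 of 48 higher and 1 lower, or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.0751). With vehicle in place of control libraries 14 were higher and 1 lower (camera adjusted p = 6.78e-06, and adjusted p = 0.346 with an estimated correlation). With the myogenic score as a covariate 2 were higher and 2 lower. The lists of Hedgehog targets (19 genes, camera adjusted p = 0.241), Wnt/beta-catenin targets (22 genes, 0.318), epithelial genes (47 genes, 0.159), mural cell genes (11 genes, 0.424), erythroid genes (26 genes, 0.575), neuronal genes (25 genes, 0.870), Schwann and glial genes (22 genes, 0.431), immediate early genes (24 genes, 0.683), mitochondrially encoded genes (13 genes, 0.604) and sex-linked reporter genes (6 genes, 0.639) did not pass. The median and mean of the neuronal list (-0.02 and 0.15), the mitochondrially encoded list (0.07 and -0.04) and the sex-linked list (-0.06 and 0.15) differed in sign, the camera direction being up for each. Of the lists that did not pass, 3 more did so against the vehicle libraries, though not with an estimated correlation. Erythroid genes had 12 of 26 lower and 1 higher (camera adjusted p = 9.48e-09, and adjusted p = 0.346 with an estimated correlation), mitochondrially encoded genes 7 of 13 higher (2.62e-05, and adjusted p = 0.122 with an estimated correlation), and Schwann and glial genes 1 of 22 higher (0.0323, and adjusted p = 0.564 with an estimated correlation). Only 1 of 39 Hox genes was expressed enough to be tested, with a log2 change of 0.68 that did not pass.

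Over all 17335 genes tested, 1358 were higher and 1115 lower in the knockout at an edgeR adjusted p below 0.05, of which 697 and 256 changed at least 2-fold. All 3 knockout libraries lay above or below all 3 control libraries for 31.9% of the genes, against 10% by chance. Without control 2 the counts were 875 and 624, and without knockout 2 they were 808 and 552.

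**Figure D3:**
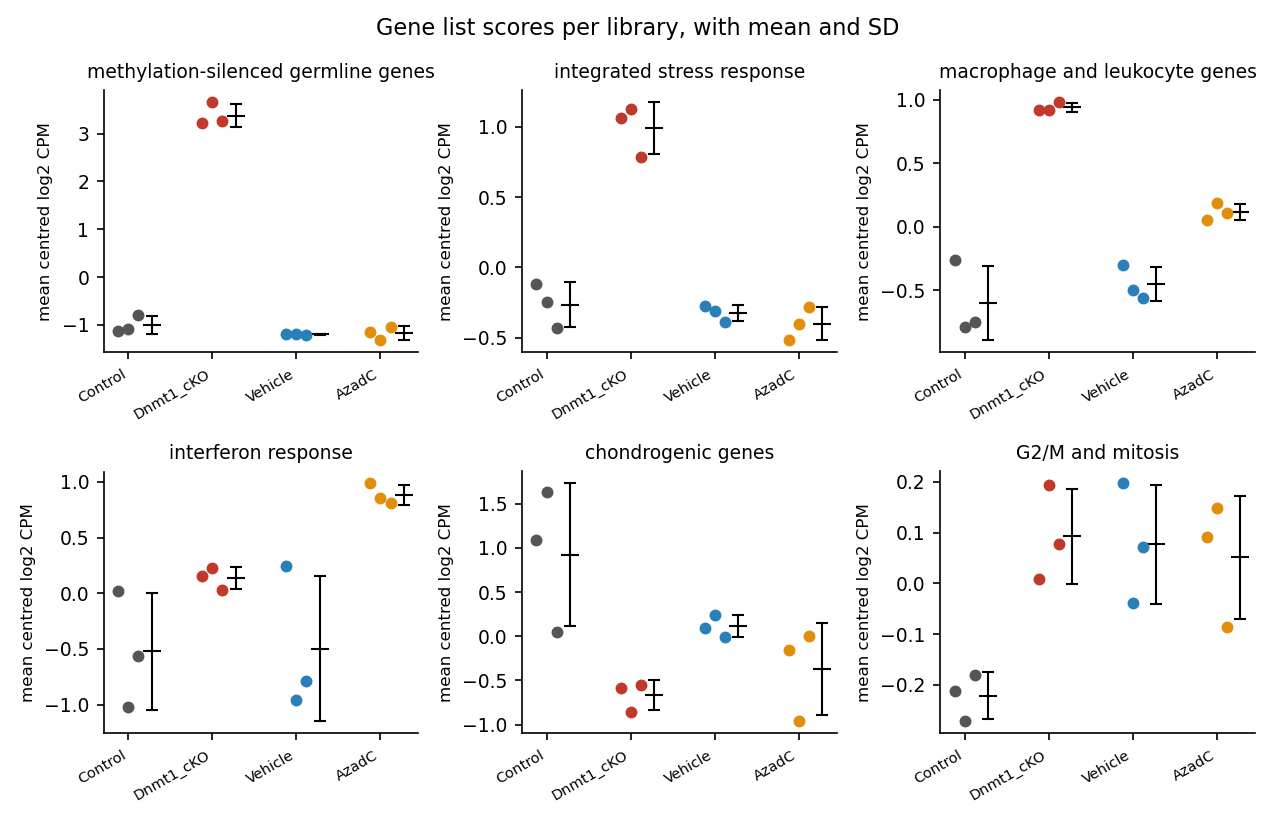
Mean centred log2 CPM of 6 gene lists in each library, points for libraries and bars for the mean and SD (n = 3). Germline, stress response and macrophage scores were highest in the knockout libraries. Interferon scores were highest in the AzadC libraries (0.81 to 0.99).

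The second comparison, AzadC against vehicle, asked what the methyltransferase inhibitor changes in wild type shelves. Interferon-induced genes and macrophage genes had higher levels in the AzadC libraries as groups, although no single member passed over all genes by edgeR or voom, where DESeq2 called 14 and 6. Gbp2, an interferon-induced GTPase, had 1.19 ± 0.665 CPM with AzadC and 0.0904 ± 0.0344 with vehicle (log2 change 3.58, SE 0.62, edgeR adjusted p = 0.0979), and B2m 79.5 ± 7.88 and 56.5 ± 2.98 CPM (log2 change 0.49, SE 0.08, edgeR adjusted p = 0.0979). Of 47 interferon genes 0 passed by edgeR over all genes, with 31 higher at an unadjusted p below 0.05, 14 higher by DESeq2 and 0 by voom. 27 were higher when adjusted over the list alone (camera adjusted p = 2e-53, and adjusted p = 0.0313 with an estimated correlation). That last count was 42 without vehicle 1, whose list score of 0.25 stood apart from -0.96 and -0.78 in the other vehicle libraries, while the AzadC libraries had 0.99, 0.86 and 0.81. Without vehicle 1, 5 interferon genes passed over all genes, and without AzadC 2 just 1 did.

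The macrophage genes Fcgr3, an immunoglobulin receptor, and Tyrobp, a signalling adaptor, had log2 changes of 1.25 (SE 0.19, edgeR adjusted p = 0.0666) and 0.96 (SE 0.17, edgeR adjusted p = 0.114). Both passed without vehicle 1 (0.0323 and 0.0497). In the macrophage list 0 of 31 genes passed by edgeR over all genes, with 19 higher at an unadjusted p below 0.05, 6 by DESeq2 and 0 by voom. 17 were higher when adjusted over the list alone (camera adjusted p = 3.47e-21, and adjusted p = 0.0313 with an estimated correlation). This count was 9 without AzadC 2, 10 without vehicle 2 and 7 without vehicle 3, and without vehicle 1 there were 2 over all genes. Neuronal genes were lower as a group, with 0 of 25 past the threshold by edgeR and by voom, 1 by DESeq2, 4 at an unadjusted p below 0.05 and 1 when adjusted over the list alone (camera adjusted p = 0.000822, and adjusted p = 0.0313 with an estimated correlation). Tubb3, a neuronal tubulin, changed by -0.95 log2 units (SE 0.25, edgeR adjusted p = 0.381) and the RNA-binding protein gene Elavl2 by -0.46 (SE 0.16, 0.633).

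The vessel genes Flt1 and Icam2 had log2 changes of 0.55 (SE 0.12, edgeR adjusted p = 0.223) and 0.58 (SE 0.13, 0.243). The endothelial list had 2 of 30 genes higher when adjusted over the list alone (camera adjusted p = 4.48e-09, and adjusted p = 0.291 with an estimated correlation), and over all genes 0 by edgeR and voom, 2 by DESeq2 and 6 at an unadjusted p below 0.05. The 2 became 0 without AzadC 2 or vehicle 3, 5 without AzadC 3, and 4 without vehicle 1 or vehicle 2. Transcripts of the mitochondrial genome such as mt-Co1 (log2 change 0.33, SE 0.06, edgeR adjusted p = 0.136) and mt-Atp6 (0.51, SE 0.13, 0.366) had 3 of 13 higher when adjusted over the list alone (camera adjusted p = 7.56e-07, and adjusted p = 0.0602 with an estimated correlation), and over all genes 0 by edgeR and voom, 2 by DESeq2 and 5 at an unadjusted p below 0.05. Camera also placed 4 further lists past its threshold, and each lost the call with an estimated correlation. These were the osteogenic genes, upward (camera adjusted p = 9.27e-05, and adjusted p = 0.366 with an estimated correlation), the hypoxia and glycolysis genes, upward (9.27e-05, and adjusted p = 0.366 with an estimated correlation), the chondrogenic genes, downward (0.00551, and adjusted p = 0.822 with an estimated correlation), and the Wnt/beta-catenin targets, upward (0.0465, and adjusted p = 0.384 with an estimated correlation). In these 4 lists edgeR and voom called 0 genes and DESeq2 1, 1, 0 and 1, with 8, 5, 1 and 6 at an unadjusted p below 0.05. Adjusted over the list alone 0, 1, 0 and 1 passed. 7 and 5 osteogenic genes did so without AzadC 2 and vehicle 2, 2 hypoxia genes without vehicle 1 or vehicle 2 and 0 without vehicle 3, and 2 Wnt targets without vehicle 3. Among members, Runx2 had a log2 change of 0.52 (SE 0.14), Postn of 0.90 (SE 0.27), Vegfa of 0.30 (SE 0.06), Col9a3 of -1.10 (SE 0.52) and Epyc of -2.70 (SE 1.06), with edgeR adjusted p of 0.422, 0.534, 0.136, 0.784 and 0.722. DESeq2 called Gbp2, B2m, Fcgr3, Tyrobp, Tubb3, Flt1, Icam2, Runx2, Vegfa, mt-Co1 and mt-Atp6 (adjusted p 4.64e-06 for Fcgr3 to 0.0421 for Runx2). Without a filter on low counts edgeR called Gbp2, B2m, Fcgr3, Tyrobp, Tubb3, Flt1, Runx2, Postn, mt-Co1 and mt-Atp6 (adjusted p 0.000532 for Postn to 0.0155 for mt-Co1).

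Single genes past the threshold were 1 higher and 1 lower of 17335, with 1105 at an unadjusted p below 0.05. Cav1, the coat protein of caveolae (chromosome 6, 17306335 to 17341452), rose from 14.6 ± 1.88 to 26.4 ± 1.79 CPM, or by 0.86 log2 units (SE 0.11, edgeR adjusted p = 0.0232). It stood at 22.3 ± 1.24 CPM in the control and 18.8 ± 1.26 in the knockout group, both above vehicle. It lost the call without AzadC 1 (0.0888), AzadC 2 (0.0688), AzadC 3 (0.148), vehicle 2 (0.0764) or vehicle 3 (0.0944). Fits with only these groups (0.0726) or with the replicate number as a block (0.0813) did not call it either. Nor did those with the Y-linked level as a covariate (0.0510) or against a 1.2-fold change (0.148). The alternatives gave 5.63e-08 to 0.148. Meioc, a gene needed in meiosis (chromosome 11, 102663716 to 102682237), went from 23.9 ± 4.71 CPM with vehicle to 1.47 ± 0.295 with AzadC, a log2 change of -3.99 (SE 0.25, edgeR adjusted p = 1.05e-05). In the control group Meioc stood at 0.950 ± 0.208 CPM. It was the 1 of 46 germline genes that passed, and the germline list did not (camera adjusted p = 0.226, median log2 change 0.15). Dnmt1 changed by -0.05 log2 units (SE 0.07, edgeR adjusted p = 0.956), Dnmt3a by 0.04 (0.955), Dnmt3b by -0.05 (0.973), Uhrf1 by -0.09 (0.924) and Tet1 by -0.07 (0.956). The libraries of the 2 groups were fully apart for 11.9% of the genes, against 10% by chance. DESeq2 called 81 genes higher and 8 lower. Without vehicle 1 the edgeR counts were 16 and 1, without AzadC 1 or AzadC 3 they were 0 and 1, and without vehicle 3 they were 0 and 2.

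Between the 2 kinds of wild type shelves, vehicle against control, the vehicle treatment and anything else that differs between these groups act together. Bone genes were lower and red blood cell and cell division genes higher in the vehicle libraries. None of these list calls held with an estimated correlation (adjusted p = 0.131 for osteogenic, 0.327 for erythroid and G2/M and 0.337 for S-phase genes with an estimated correlation). Ibsp, the bone sialoprotein, went from 7.68 ± 6.36 CPM in control to 0.0888 ± 0.0931 with vehicle, a log2 change of -6.63 (SE 0.96, edgeR adjusted p = 0.00395), which was -5.69 without control 2, -7.53 without vehicle 1 and -5.89 without vehicle 2. Bmp3, Alpl and Postn, all expressed in bone-forming tissue, fell by 2.27 (SE 0.25), 2.38 (SE 0.31) and 1.96 (SE 0.27), with edgeR adjusted p of 0.000769, 0.0021 and 0.00362. Of 30 osteogenic genes 13 were lower, and 19 when adjusted over the list alone (camera adjusted p = 4.9e-14, and adjusted p = 0.131 with an estimated correlation). 8 were lower without control 2 or vehicle 1 and 7 without vehicle 3. In the chondrogenic list 4 of 28 were lower, and 14 when adjusted over the list alone (camera adjusted p = 6.34e-06, and adjusted p = 0.523 with an estimated correlation), with 1 without control 2, 13 without control 3 and 0 without any of the vehicle libraries in turn. Adjusted over the list alone that count was 2 without control 2 and 6 without vehicle 3.

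Hemgn, a nuclear protein of red cell precursors, rose by 2.95 log2 units (SE 0.46, edgeR adjusted p = 0.00577), and the embryonic globin gene Hbb-bh1 from 92.3 ± 34.2 to 363 ± 71.6 CPM, or by 1.97 (SE 0.28, edgeR adjusted p = 0.00382). In the erythroid list 11 of 26 genes were higher, and 18 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 4.9e-14, and adjusted p = 0.327 with an estimated correlation). The count was 7 without control 1, control 3 or vehicle 3, 17 without control 2 and 4 without vehicle 1. Ncapd2 and the spindle checkpoint gene Bub1b rose by 0.43 (SE 0.06) and 0.46 (SE 0.08), with edgeR adjusted p of 0.00577 and 0.00848, but did not pass against a 1.2-fold change (over the alternatives 2.30e-07 to 0.157 and 5.95e-06 to 0.142). G2/M genes had 18 of 51 higher, and 40 when adjusted over the list alone (camera adjusted p = 6.54e-24, and adjusted p = 0.327 with an estimated correlation). Without control 2, control 3, vehicle 1 and vehicle 3 the 18 became 5, 9, 2 and 2, and the 40 became 26 without control 2 and 21 without vehicle 1. S-phase genes had 6 of 49 higher, and 20 when adjusted over the list alone (camera adjusted p = 8.31e-13, and adjusted p = 0.337 with an estimated correlation). The 6 became 0 without control 2, control 3, vehicle 1 or vehicle 3, and the 20 became 4, 12, 4 and 12 in the same order. With all libraries DESeq2 called 14 S-phase genes higher and voom 5.

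Dnmt1 was 0.72 log2 units higher with vehicle (SE 0.07, edgeR adjusted p = 0.000286), and the methylation machinery list had 2 of 21 genes higher, also when adjusted over the list alone (camera adjusted p = 0.00134, and adjusted p = 0.131 with an estimated correlation). Of imprinted genes, Magel2 rose by 1.41 (SE 0.26, edgeR adjusted p = 0.0141, and 0.0562 without vehicle 3) and Plagl1 fell by 1.04 (SE 0.15, edgeR adjusted p = 0.00362), while the imprinted list did not pass (camera adjusted p = 0.141). The epidermal keratin gene Krt5 fell by 2.50 (SE 0.39, edgeR adjusted p = 0.00626). 6 of 47 epithelial genes were lower, and 8 when adjusted over the list alone, although the list's median was 0.15, its mean -0.21 and its camera direction up (camera adjusted p = 0.944). The 6 became 3 without control 3, 2 without vehicle 1 and 1 without vehicle 3. Tnfrsf19, a target of Wnt signalling, fell by 1.33 (SE 0.17, edgeR adjusted p = 0.0017), and Wnt/beta-catenin targets as a list were lower (camera adjusted p = 0.000964, and adjusted p = 0.327 with an estimated correlation), with 5 of 22 lower over all genes and 8 lower and 1 higher when adjusted over the list alone. The 5 became 2 without control 1, control 2 or vehicle 3, 1 without control 3 or vehicle 1, and 3 without vehicle 2. Of 13 mitochondrially encoded genes 2 were lower, and 6 when adjusted over the list alone (camera adjusted p = 4.73e-06, and adjusted p = 0.131 with an estimated correlation). The 2 genes, mt-Atp8 and mt-Nd6, lost their calls in 3 and 4 of 6 fits with 1 library left out. Those fits gave edgeR adjusted p of 0.0725 to 0.1105 and 0.0791 to 0.133. DESeq2 called 5 genes of this list lower and voom 3. Of 48 protocadherins 2 were lower, and 5 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.000388, and adjusted p = 0.427 with an estimated correlation). Of 28 BMP and TGF-beta targets 5 were lower, 2 without control 2, vehicle 1 or vehicle 3, and when adjusted over the list alone 7 were lower and 1 higher, with 11 lower without control 3 or vehicle 2 (camera adjusted p = 0.0105, and adjusted p = 0.41 with an estimated correlation). The myogenic list passed upward (camera adjusted p = 0.00125, and adjusted p = 0.816 with an estimated correlation), with 0 of 38 genes past the threshold by edgeR and voom, 1 lower by DESeq2, and 3 higher and 1 lower at an unadjusted p below 0.05.

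Large single rises with vehicle were in Meioc (log2 change 4.64, SE 0.26, edgeR adjusted p = 7.58e-07), Hemgn, Pklr (2.38, SE 0.53, 0.0276) and Fibcd1 (2.37, SE 0.38, 0.00717), and the largest falls in Ibsp, Cfap91 (-6.46, SE 1.31, 0.0204), Aspn (-4.81, SE 0.78, 0.00792), Scin (-4.14, SE 0.89, 0.025) and Wnt16 (-4.13, SE 0.58, 0.00362). Pklr lost its call without control 2 or 3 or vehicle 1 or 3 (edgeR adjusted p 0.0701, 0.0793, 0.106 and 0.0562), Cfap91 without control 2 or vehicle 1, 2 or 3 (0.0503, 0.079, 0.0651 and 0.0909) and Scin without control 2 or vehicle 1 or 3 (0.101, 0.105 and 0.112). Cfap91 and Scin did not pass with limma-voom, nor Pklr and Scin against a 1.2-fold change. Over the alternatives other than leaving out 1 library, the adjusted p was 0.00113 to 0.0659 for Pklr, 3.20e-08 to 0.152 for Cfap91 and 1.10e-06 to 0.0796 for Scin. Fitted log2 changes also moved, for Cfap91 without vehicle 1 (-7.08) or vehicle 3 (-5.87), and Scin without control 2 (-3.12) or vehicle 2 (-4.96). Over all genes 253 were higher and 357 lower with vehicle, 40 and 165 of them at least 2-fold. The libraries of the groups were fully apart for 22.7% of the genes, against 10% by chance. The counts were 97 and 185 without control 2, 123 and 215 without control 3, 46 and 90 without vehicle 1, and 52 and 85 without vehicle 3.

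**Figure D4:**
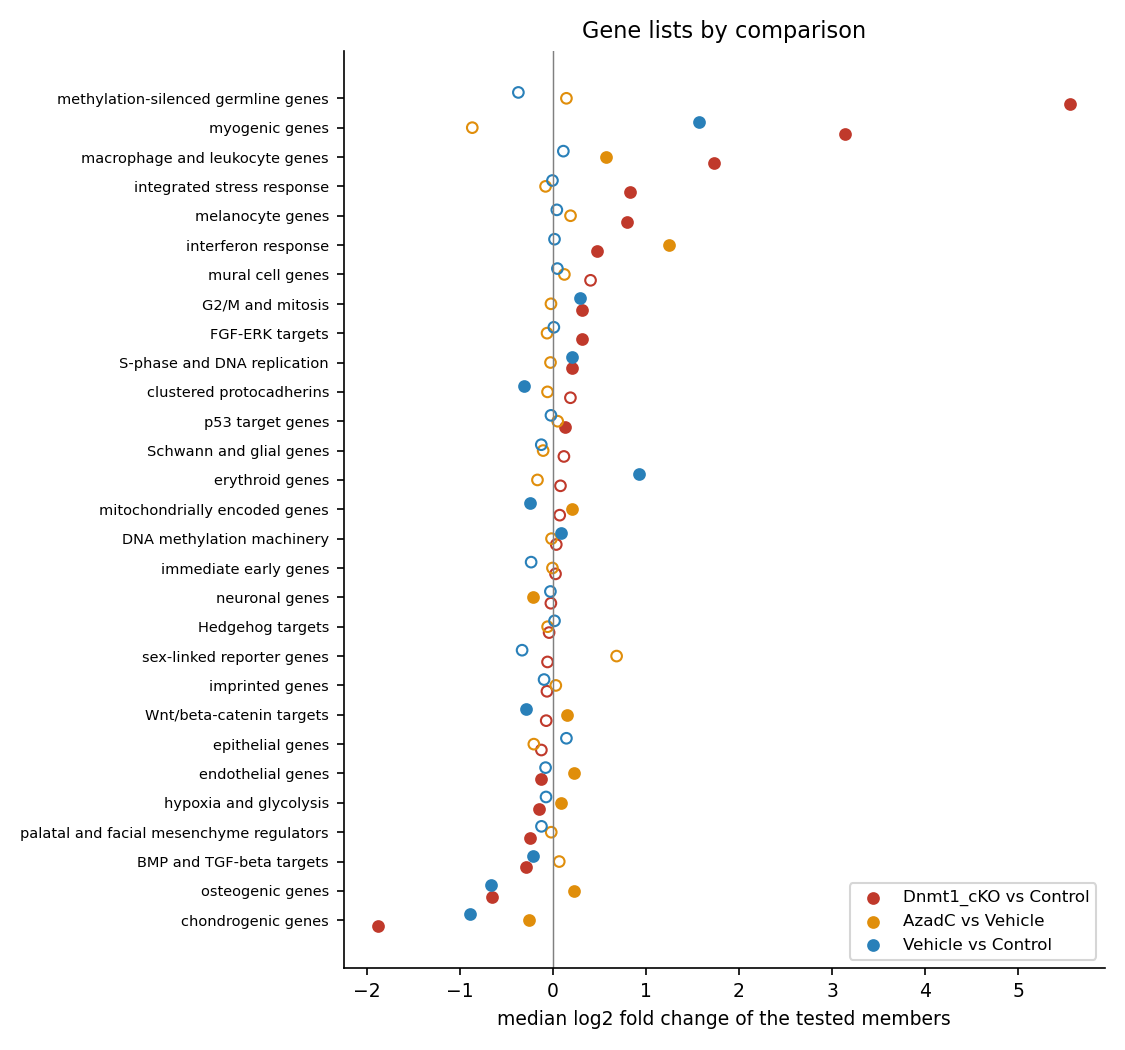
Median log2 fold change of the tested members of each gene list (horizontal axis), by comparison; filled points passed camera at an adjusted p below 0.05 and open points did not. The germline list had a median of 5.56 in the knockout and 0.15 with AzadC, and the interferon list 0.47 and 1.25.

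Whether the knockout and AzadC act on the same genes was tested as the difference between the 2 effects, knockout against control and AzadC against vehicle, which share no libraries. The knockout effect was higher than the AzadC effect for stress response, germline and macrophage genes, and lower for bone genes. No such list call held with an estimated correlation (adjusted p = 0.109, 0.0889, 0.136 and 0.225 with an estimated correlation). With AzadC the stress response list had a median log2 change of -0.08 (camera adjusted p = 0.216) and the osteogenic list one of 0.23. Slc7a5 and Asns differed by 2.04 (SE 0.18) and 1.90 (SE 0.18) log2 units, with edgeR adjusted p of 3.53e-05 and 6e-05, and 20 of 30 stress response genes had a higher effect in the knockout, or 22 higher and 1 lower when adjusted over the list alone (camera adjusted p = 3.22e-19, and adjusted p = 0.109 with an estimated correlation). Among germline genes Stag3 differed by 1.91 (SE 0.18, edgeR adjusted p = 6.39e-05) and 15 of 46 were higher, or 21 higher and 1 lower when adjusted over the list alone (camera adjusted p = 9.7e-28, and adjusted p = 0.0889 with an estimated correlation). By edgeR 9 were higher without knockout 2. With all libraries DESeq2 called 26 of the 46 higher and voom 31. Meioc differed by 6.59 (SE 0.36, edgeR adjusted p = 3.85e-07), being higher in the knockout than in control and lower with AzadC than with vehicle. The vehicle group stood apart at 23.9 ± 4.71 CPM, above the knockout at 5.82 ± 1.5, so that the direction in the knockout depends on the wild type group used. Csf1r and Adgre1 differed by 1.86 (SE 0.19) and 1.78 (SE 0.24), with edgeR adjusted p of 0.000131 and 0.00164. Of 31 macrophage genes 21 had a higher and 1 a lower effect in the knockout when adjusted over the list alone, and 11 and 1 over all genes (camera adjusted p = 1.21e-10, and adjusted p = 0.136 with an estimated correlation). The 11 became 6 without AzadC 1, control 2 or knockout 2, 7 without AzadC 3, knockout 1, knockout 3, vehicle 1 or vehicle 3, and 17 without control 1.

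Runx2, Bmp3 and Sox9 differed by -1.68 (SE 0.20), -2.81 (SE 0.36) and -1.62 (SE 0.25), with edgeR adjusted p of 0.00049, 0.000945 and 0.00341. Of 30 osteogenic genes 9 had a lower effect in the knockout, or 18 when adjusted over the list alone (camera adjusted p = 1.58e-09, and adjusted p = 0.225 with an estimated correlation), and 5 without AzadC 1 or knockout 2. The control libraries stood apart for Bmp3, and the knockout libraries for Sox9. For Runx2 the lowest control library (84.1 CPM) lay next to the highest AzadC library (84.0 CPM). The lowest AzadC library (72.9 CPM) lay above the highest vehicle library (59.8 CPM) for that gene. Bmp3 averaged 5.71 ± 1.04 CPM in the knockout, 23.3 ± 7.3 in control, 4.79 ± 0.665 with vehicle and 8.26 ± 2.23 with AzadC, and Runx2 44.9 ± 7.67, 100.1 ± 15.2, 53.6 ± 7.13 and 76.8 ± 6.24 in the same order, as against 29.2 ± 5.05, 101.5 ± 31, 92.5 ± 4.04 and 81.6 ± 5.61 for Sox9. The osteogenic list of the knockout had, against the vehicle libraries, 5 genes higher and 3 lower (camera adjusted p = 0.34). For 28 chondrogenic genes the list test also passed (camera adjusted p = 1.16e-06, and adjusted p = 0.353 with an estimated correlation), with 4 lower over all genes, and 20 lower and 1 higher when adjusted over the list alone, or 9 lower without AzadC 3 and 13 without control 2. The 4 became 2 without AzadC 1, AzadC 3, control 2, vehicle 1, vehicle 2 or vehicle 3, 9 without AzadC 2, 16 without control 3 and 1 without knockout 2. Vegfa, an angiogenic growth factor, and Pdk1, a kinase that limits pyruvate oxidation, differed by -0.56 (SE 0.08) and -1.04 (SE 0.15), with edgeR adjusted p of 0.00269 and 0.00239. Of 37 hypoxia and glycolysis genes 5 were lower, and 12 lower and 1 higher when adjusted over the list alone (camera adjusted p = 9.21e-06, and adjusted p = 0.269 with an estimated correlation). The 5 became 3 without AzadC 1, knockout 1 or knockout 2 and 2 without vehicle 3. Endothelial genes had 4 of 30 lower, and 11 when adjusted over the list alone (camera adjusted p = 5.5e-08, and adjusted p = 0.269 with an estimated correlation). The 4 became 2 without control 2, knockout 2 or vehicle 3, and the 11 became 5 without AzadC 2, control 2 or knockout 3, 7 without AzadC 1, control 1 or vehicle 2, 6 without vehicle 3 and 17 without knockout 1. The interferon list was lower in the knockout effect than in the AzadC effect (camera adjusted p = 3.06e-06, and adjusted p = 0.375 with an estimated correlation), with 2 of 47 genes lower, also when adjusted over the list alone. Without vehicle 1 these counts were 8 and 20, without control 2 they were 0 and 13, and without AzadC 2 the last was 5. Without control 1 or control 3 both were 1, and without AzadC 1, AzadC 3, vehicle 2, vehicle 3 or any of the knockout libraries both were 0. The 2 genes were Ifih1 and Ifi35, at -1.54 (SE 0.37) and -1.64 (SE 0.43), edgeR adjusted p of 0.0359 and 0.0474. Ifih1 lost its call in 8 of 12 fits with 1 library left out (0.0545 to 0.0965), all but those without AzadC 2, control 1, control 3 or vehicle 1, and Ifi35 in 11 of 12 (0.0539 to 0.109), all but that without vehicle 1. Neither passed with the Y-linked covariate or against a 1.2-fold change, nor Ifih1 with the replicate number as a block, nor Ifi35 with the myogenic score. Over the alternatives other than leaving out 1 library, the adjusted p was 0.000844 to 0.0695 for Ifih1 and 0.00594 to 0.169 for Ifi35. Dnmt1 differed by -0.47 (SE 0.10, edgeR adjusted p = 0.0209), and not past the threshold without control 2 (0.0524), knockout 2 (0.0659) or vehicle 3 (0.0502), against a 1.2-fold change or with the myogenic score (over the alternatives 0.000465 to 0.162).

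The genes with the largest differences included ENSMUSG00000120900, Xlr3c, Xlr4c, Tex19.1 and Magea13, at 17.6, 28.6, 8.33, 12.3 and 25.8 CPM in the knockout and below 0.11 CPM in the control, vehicle and AzadC groups, with edgeR adjusted p of 0.00777, 0.0406, 0.0119, 0.0127 and 0.003. No fold is given for these, since each had 5 or fewer counts over the AzadC and over the vehicle libraries. The call of Tex19.1 was lost without vehicle 2 and that of Xlr4c without vehicle 3 (edgeR adjusted p = 1.0 for both). That of Xlr3c was lost in 8 of 12 such fits (0.0521 to 1.0), all but those without AzadC 2, control 1, control 3 or knockout 3. The largest lower differences were in Scin (-6.98, SE 1.47), Aspn (-4.71, SE 1.04), Ltbp2 (-4.40, SE 0.65), Matn4 (-4.27, SE 0.87) and Pcp4 (-4.20, SE 0.96). Mean levels in the knockout, control, vehicle and AzadC groups were 0.0959, 7.04, 0.375 and 0.708 CPM for Scin and 3.57, 27.1, 0.888 and 3.13 CPM for Aspn. With limma-voom Scin (adjusted p over the alternatives 5.29e-07 to 0.181), Aspn (1.01e-07 to 0.107), Matn4 (3.17e-09 to 0.0935) and Pcp4 (5.09e-07 to 0.0553) did not pass. Nor did Xlr3c against a 1.2-fold change, with the myogenic score or with the replicate number as a block (2.56e-06 to 0.0665). Among these lower differences the fitted value moved for Scin without AzadC 3 (-5.93), control 2 (-5.95), knockout 1 (-8.68) or vehicle 2 (-7.80), Aspn without AzadC 3 (-3.61), Matn4 without AzadC 3 (-3.45) or control 2 (-3.56), and Pcp4 without vehicle 2 (-4.90). Ltbp2 passed in all 12 fits with 1 library left out. Matn4 failed without AzadC 3 (edgeR adjusted p = 0.0604) or knockout 2 (0.0549), and Scin without AzadC 3 (0.108), control 2 (0.0501) or knockout 2 (0.0569). Aspn failed without AzadC 1 (0.0501), AzadC 3 (0.109), control 2 (0.0627), knockout 2 (0.0606), vehicle 1 (0.0541) or vehicle 3 (0.0536), and Pcp4 failed in all but the 5 fits without AzadC 2, control 1, control 3, knockout 3 or vehicle 2 (0.0531 to 0.0823). In all 382 genes had a higher and 381 a lower effect in the knockout. The counts were 196 and 189 without AzadC 1, 211 and 178 without AzadC 3, 200 and 192 without control 2, 232 and 252 without knockout 1, 168 and 160 without knockout 2, 202 and 225 without vehicle 1, and the lower count 238 without vehicle 3.

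G2/M genes had 5 of 51 higher and myogenic genes 4 of 38, and 27 higher, and 37 higher and 1 lower, when adjusted over the list alone (camera adjusted p = 5.41e-16 and 4.31e-10, and adjusted p = 0.269 and 0.378 with an estimated correlation). With 1 library left out these did not hold: the 5 became 0 without AzadC 1, AzadC 3, control 2, knockout 2 or vehicle 1, 1 without control 3 or vehicle 3, 3 without knockout 1 or knockout 3, 9 without AzadC 2 and 10 without vehicle 2. The 27 became 0 without knockout 2, 13 without AzadC 3, 16 without control 2 and 12 without vehicle 1. The 4 myogenic genes became 0 without AzadC 1, AzadC 2, control 2, control 3, knockout 1, knockout 2 or vehicle 2, 1 without vehicle 1, 9 without knockout 3 and 8 without vehicle 3. The 37 became 18 without knockout 1 and 0 without vehicle 2. With all libraries DESeq2 called 15 G2/M and 13 myogenic genes higher, and voom 6 and 0.

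Further lists passed camera in the difference and lost the call with an estimated correlation. Palatal and facial regulators had 9 of 62 lower (5 without AzadC 3, knockout 2 or vehicle 1), and 15 lower and 1 higher when adjusted over the list alone, with 9 lower without vehicle 1 and 2 or 0 higher without AzadC 1 or vehicle 1 (camera adjusted p = 0.00472, and adjusted p = 0.269 with an estimated correlation). BMP and TGF-beta targets had 6 of 28 lower, and 7 lower and 1 higher when adjusted over the list alone, the 1 being 2 without control 1 or knockout 3 and 0 without any AzadC library, knockout 1, knockout 2, vehicle 1 or vehicle 2 (camera adjusted p = 0.00029, and adjusted p = 0.247 with an estimated correlation). Wnt/beta-catenin targets had 2 of 22 lower and 1 higher, and 6 and 3 when adjusted over the list alone (camera adjusted p = 0.0416, and adjusted p = 0.375 with an estimated correlation). The 1 became 0 without AzadC 1, control 2 or vehicle 1 and 2 without control 1, and the 6 became 3 without AzadC 3 or knockout 2. S-phase genes had 1 of 49 higher, and 5 when adjusted over the list alone (camera adjusted p = 1.14e-07, and adjusted p = 0.353 with an estimated correlation). These counts were 9 and 17 without AzadC 2 and 3 and 10 without control 1, the last was 14 without vehicle 2, the first was 0 without control 3, and both were 0 without AzadC 1, AzadC 3, control 2, knockout 1, knockout 2, vehicle 1 or vehicle 3. FGF-ERK targets had 1 of 19 higher, also over the list alone (camera adjusted p = 0.0177, and adjusted p = 0.382 with an estimated correlation), and melanocyte genes 1 of 6, or 2 when adjusted over the list alone (camera adjusted p = 0.0454, and adjusted p = 0.269 with an estimated correlation). The mitochondrially encoded list passed downward (camera adjusted p = 0.0416, and adjusted p = 0.353 with an estimated correlation), with 0 of 13 genes by edgeR, DESeq2 or voom, 2 lower at an unadjusted p below 0.05 and 0 when adjusted over the list alone.

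Across all 17335 genes the log2 changes of the 2 comparisons had a Pearson r of 0.05 and a Spearman rho of -0.01, a description over genes, which are not independent replicates. Of the 2 genes called with AzadC, 1 (Meioc) was called with the knockout against control, in the opposite direction. Its one-sided Fisher's exact p was 0.0783, the smallest that 1 gene allows there, and the other pairings of directions gave 1.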

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

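All alternatives were planned except those against the vehicle libraries and with the myogenic score, chosen after seeing the data. The replicate numbers do not pair the libraries: same-numbered deviations correlated at 0.28, 0.08 and 0.24 in knockout against control, 0.03, -0.10 and -0.06 in AzadC against vehicle, and 0.04, 0.11 and 0.14 in vehicle against control. In the knockout comparison every library correlated best with its own number, a hint from the data alone, and in the others not. With the replicate number as a block the calls of Cav1 with AzadC and of Ifih1 and Xlr3c in the difference ended, and AzadC had 0 genes higher, while the other counts stayed within 1.5 times. Dnmt1 kept its direction and call in the knockout, at -0.57 to -0.48 with 1 library left out.

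For AzadC against vehicle, genes higher (1) and lower (1) became 81 and 8 with DESeq2 and 102 and 17 with no filter; the higher count became 2 with only the groups compared, 4 with the Y-linked covariate, 0 against a 1.2-fold change and 2 with the myogenic score. For vehicle against control (253 and 357) DESeq2 gave 569 and 756, no filter 487 and 772, a 1.2-fold change 26 and 90, and only the groups compared 143 higher. For the difference (382 and 381) DESeq2 gave 755 and 704, no filter 704 and 734, a 1.2-fold change 168 and 158, and the myogenic score 201 higher. The knockout counts (1358 and 1115) became 673 and 404 against a 1.2-fold change, and 716 lower against the vehicle libraries. Of the calls against control, 742 higher and 364 lower ones were also called in the same direction against the vehicle libraries. A further 10 were called in the opposite direction. With the myogenic score as a covariate 1329 of the 2473 genes were called again. Testing against a minimum change asks more of each gene by construction; otherwise the cause was not tested.

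With 1 library left out, and so fewer samples, the counts higher and lower ran from 808 to 1262 and 552 to 969 (knockout), 0 to 16 and 1 to 2 (AzadC), 46 to 205 and 85 to 361 (vehicle), and 168 to 439 and 160 to 457 (difference). Gene lists past the threshold numbered 2 (knockout), 3 (AzadC), 0 (vehicle) and 0 (difference) with an estimated correlation, and with fry 3 for AzadC, 6 for vehicle and 11 for the difference. Named genes past it numbered 26 in the knockout against the vehicle libraries; 13 (DESeq2), 12 (no filter) and 1 (only the groups compared, block, Y-linked covariate, 1.2-fold) with AzadC; and 16 with vehicle against a 1.2-fold change, with ranges of 1 to 4 (AzadC) and 17 to 28 (vehicle) with 1 library left out.

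The sign reversed for changes that were not called, Dnmt1 with AzadC (0.015 with the Y-linked covariate), Dnmt3b with AzadC (0.011 without AzadC 3, 0.03 without vehicle 1, and -0.136 at the lowest, without AzadC 2) and Tet1 in the knockout (-0.031 without control 1, -0.05 against the vehicle libraries, and 0.175 at the highest, without control 3), and for Ncapd2, called in the knockout (-0.047 against the vehicle libraries); the cause was not tested. Depth limits the genes near 0 counts, where the fold is a bound.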

Other observations

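Gene families by name were tested among the calls of the knockout against control, as 498 families of 5 or more tested genes in each direction. They were not tested against the vehicle libraries, so whether they depend on the wild type group used is not known. These one-sided Fisher's exact tests were chosen after seeing the data. They pointed to the groups below, some of which were partly or wholly on the lists fixed beforehand. All 7 tested genes with Cct names, for subunits of the chaperonin that folds actin and tubulin, were higher (adjusted p = 8.13e-06). So were 19 of 50 Rpl genes of the large ribosomal subunit (2.58e-06), 9 of 21 nucleoporin genes (0.00274) and 6 of 6 Ms4a genes (7.47e-05). Also higher were 8 of 8 Xlr genes (1.99e-06), which share reads, 7 of 15 Tex genes (0.0108) and 7 of 10 olfactory receptor genes (0.000391). All 8 Xlr genes, 3 of the 15 tested Tex genes, 1 of the 50 Rpl genes and 1 of the 6 Ms4a genes were on the lists fixed beforehand. Collagen genes were lower in 14 of 40 cases (9.33e-05), 12 of the 40 tested being on the lists fixed beforehand, and Pcdh genes outside the clusters in 6 of 12 (0.0108) and Adamts proteases in 7 of 18 (0.0175).

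Of 623 tested X-linked genes 86 (13.8%) were higher in the knockout, against 7.61% elsewhere (odds ratio 1.94, Fisher's exact p = 2.68e-07), and 66 (10.6%) at least 2-fold, against 3.78% (odds ratio 3.02, p = 5.27e-13; 2.89 and 3.22e-12 with the Y-linked level as a covariate). X-linked genes lower were 68 (10.9%, against 6.26% elsewhere, odds ratio 1.83, Fisher's exact p = 1.86e-05). This comparison was not among the tests fixed beforehand. The higher X-linked genes include germline list members given above, such as Xlr3c, so their excess is partly the same result. Xist, the RNA that coats the inactive X, stood at 1915, 1852 and 2256 CPM in the knockout libraries, above all others, which had 1428 at most and 0.87 in AzadC 1. Its log2 change in the knockout was 0.71 (SE 0.94, edgeR adjusted p = 0.683). That fit shares its spread over all 12 libraries, AzadC 1 included, so this p does not measure the knockout and control spread alone. AzadC 1 also had the highest summed Y-linked level, 244.5 CPM.

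All tests of explanations below were chosen after the results were seen, and only the splits were planned. The 10 splits of 6 libraries are too few for a share under 0.05: the real split called 2473 genes in the knockout (highest other 2), 2 with AzadC (1) and 610 with vehicle (0). For the difference only the real one, 1 of the 60 splits drawn, called as many as 763 genes, and the highest other called 664. The 3 other splits that kept the knockout and control libraries as labelled called 440 to 664, and all that did not called 2 at most. This share therefore bears mainly on the knockout labels, for which only 10 splits exist, so it cannot exclude chance. It does not test the part of AzadC.

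The first pattern was the lower skeletal and higher mitotic genes of the knockout against the control libraries. An earlier stage of the knockout embryos stays open, since the log2 ratio of embryonic to adult globin was 0.153 (SE 0.063) above control, with all 3 libraries above all 3 controls (1.017 against 1.012 for the nearest), where vehicle stood 0.935 above; this criterion replaced, after the value was seen, one that would have argued against the explanation. More muscle in the knockout dissections is argued against for the chondrogenic genes, of which 21 of 28 stayed lower with the myogenic score as a covariate. Their median was -2.326 with it and -1.875 without it. The SE of 0.314 for this list is that of the mean over its genes and does not measure the spread between libraries. Control libraries that stand apart from other wild type shelves were a further explanation. The knockout scores were 0.16 (SE 0.095) above vehicle for the osteogenic and 0.016 for the mitotic list, so these parts depend on the wild type group used. Against vehicle the chondrogenic median was -0.737 in place of -1.875, with a score still at -0.775 (SE 0.122), so part of that fall remained against either group. Vehicle may itself differ in stage or background, so which wild type group stands apart cannot be told. An effect of the Dnmt1 deletion on cartilage genes stays open as a hypothesis.

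The second pattern was the interferon list with AzadC. That 1 library decides it is argued against by the count adjusted over the list alone, at least 21 (27 with all libraries) whichever library was left out. A larger share of macrophages in the AzadC libraries cannot be told apart from an induction in other cells: the interferon score rose 2.43 (SE 0.766) times as much as the macrophage score, against 0.427 in the knockout, and lay above 1 by less than 2 of its SE. Csf1r averaged 36.8 CPM with AzadC, 26.4 with vehicle and 92.1 in the knockout; 31 of 32 macrophage list genes were tested in these shelves and 0 are on another list. An effect of the drug is among what stays open.

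The third pattern was the difference between vehicle and control libraries, Dnmt1 included. An earlier stage of the vehicle embryos may be part of it, since the globin ratio was 0.935 (SE 0.227) higher. A different genetic background may be another part: over the 22 called pseudogenes the knockout sat at 0.092 (SE 0.152) of the way from control to vehicle, against 0.568 for the other called genes, although pseudogenes were not called more often than other genes (22 of 601, Fisher's exact p = 0.821). That SE is over the 22 genes and does not measure the spread between libraries. The genes were also picked by their difference in these same libraries, so the value does not decide the question. Lower proliferation of the control shelves does not reach the Dnmt1 difference, 0.717 (SE 0.072) against at most 0.416 (E2f2) in the S-phase list. The treatment itself stays open and untested.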
